A study of Homo sapiens with 18 samples.

How the data were processed

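RNA was sequenced from ZR-75-1 cells, an established luminal breast cancer line that carries the estrogen receptor. A control line and a line with a knockdown of ADAR, the enzyme that turns adenosine into inosine in double-stranded RNA, were each left untreated, given DMSO or given 100 nM triptolide for 16 h. Each of the 6 groups held 3 libraries, 18 in all, numbered as biological replicates 1 to 3. Per the labels, the libraries came from a stranded total RNA kit, so they also hold RNA without a poly(A) tail.

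The deposited files hold raw counts per gene, one library per file, with no normalization. According to their processing notes, the authors aligned reads to hg19 with STAR 2.4.2a, counted them with HTSeq 0.6.1 and compared groups with DESeq2 1.4.5 in R 3.1. The strand setting of the counting is not stated. Each file lists 60252 gene IDs, of which 58821 (97.6%) were matched to GENCODE release 44 mapped to GRCh37 for symbols and positions. The 5 tallies of reads given to no gene were left out of library sizes and tests. Counts in genes came to between 26.7e6 and 35.7e6 per library. The 95% Wilson interval of a share of counts in one library reached at most 0.019 percentage points on either side. Such intervals, and floors of 3 counts over a group for genes without counts, cover counting error only. No library was a copy of another: the lowest chi-square per degree of freedom between replicates was 62.

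Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in one fit of the 18 libraries with 12 residual degrees of freedom. Genes passing the low-count filter of that package by group numbered 21285. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and tests are two-sided. Fold changes are log2 values with standard errors (SE), taken as the change divided by the square root of its F statistic. Levels are TMM-scaled counts per 1e6 counts (CPM) with the standard deviation (SD) over 3 libraries.

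Whether equal replicate numbers pair libraries was checked on the residuals of each library from its group. Libraries of different groups with the same number correlated at r between 0.31 and 0.69 across genes (45 pairs), those with different numbers between -0.52 and 3.4e-05 (90 pairs), and 18 of 18 libraries matched their own number best. The numbers therefore mark pairs, and a fit with the replicate number as a block (10 residual degrees of freedom) is given beside results that it changes. The fit without the block stays first because it was chosen before the data were examined, like the comparisons, gene lists, naming rule and alternatives, except where an alternative is said to have been added. Counts were also simulated from the blocked fit, which suits that fit by construction, with changes given to genes above 1 CPM on average. For changes of 2-fold, the fit without the block recovered 12% of these genes in the DMSO knockdown comparison and the blocked fit 76%. The shares therefore do not show which fit is better for the real counts. At 4-fold they recovered 86% and 100%, and for the interaction 48% and 92%. False calls numbered 0 without the block in each, and 9 with it for DMSO, 3 for the knockdown comparison in triptolide and 8 for the interaction.

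The 8 comparisons were knockdown against control in each treatment, triptolide against DMSO in each line, the interaction of both, and DMSO against untreated in each line. The 22 gene lists were interferon-stimulated genes, NF-kB inflammatory targets, integrated stress response targets of ATF4, p53 targets, S phase genes, G2 and M phase genes, DNA repair and checkpoint genes, estrogen receptor targets and luminal factors, mesenchymal and basal markers, immediate early and short-lived mRNAs, BCL2 family and apoptosis regulators, mitochondrially encoded mRNAs, cytoplasmic ribosomal proteins, glycolysis enzymes, nuclear oxidative phosphorylation genes, replication-dependent histones, ZNF-named zinc finger genes, small nucleolar RNA host genes, RNA polymerase III transcripts, mRNA decay machinery, RNA polymerase II and TFIIH subunits, and edited mRNAs. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares the list with the other genes, and again with an estimated correlation. The fry test, which asks whether a list's genes move one way on balance, was run beside them. List p-values were adjusted over the 22 lists within a comparison. A list's median includes genes at 0 counts in a group, whose fitted changes are no bounds.

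The genes named were ADAR, ADARB1 and ADARB2. In addition, up to 8 higher and 8 lower genes were taken for the knockdown without triptolide and for triptolide, with the largest smaller change of both comparisons, calls in both, non-overlapping libraries and at least 1 CPM. Up to 5 in each direction were taken by fold for the knockdown in triptolide and for DMSO, up to 8 for the interaction, and up to 4 members with the smallest p for each list described. Other genes are said to have been chosen after their values were seen. Markers of leukocytes, stroma, endothelium, luminal and basal-like epithelium were read as levels. RNA of the Y chromosome and XIST was not examined as a result.

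Alternatives were RLE factors, library size alone, scaling to the 13 mitochondrially encoded mRNAs, which RNA polymerase II does not make, DESeq2 1.42.0, no filter and a filter of 1 CPM in 3 libraries, only the libraries compared, the replicate block, a test against a fold of 1.5, untreated in place of DMSO, shares without ribosomal RNA, and leaving out each library. With a single library left out the fit had no replicate block, so replicate numbers were unbalanced between the groups compared. Changes of a call there can reflect differences between replicate numbers. Leaving out all libraries of a replicate number, which keeps the balance, was added after seeing the data. A call is said to be reversed where the direction changed and the default or the alternative value was called, so many reversed calls were no longer called. Other splits of the libraries were counted as well.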

Results

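The data were total RNA profiles of 18 ZR-75-1 libraries in 6 groups of 3. Counts in genes per library, in units of 1e6, averaged 30.5 ± 2.9 (SD, n = 3) in untreated, 30.6 ± 2.9 in DMSO and 29 ± 1.57 in triptolide control cells. In knockdown cells they averaged 29.2 ± 2.15, 30.4 ± 2.17 and 31.5 ± 4.03. Mitochondrial ribosomal RNA took 20.2 to 37.1% of counts in untreated and DMSO libraries and 42.7 to 55.2% in triptolide libraries. Of the 14 luminal epithelial markers, 14 reached a mean of 1 CPM, with KRT8, a keratin of simple epithelia, at 2730 CPM. Basal-like markers reached it for 6 of 11, leukocyte markers for 3 of 14 (HLA-DRA at 138 CPM), stromal markers for 3 of 11 and endothelial markers for 2 of 7. None of these markers was called between knockdown and control without triptolide by edgeR.

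ADAR mRNA, the target of the knockdown, was lower in the knockdown library than in the control library of the same number in 9 of 9 pairs. In untreated and DMSO cells it stood between 51 and 77.5% of control, and under triptolide between 31.2 and 44.4%. Mean levels were 479 ± 184 CPM (SD, n = 3) in untreated control and 295 ± 87 in untreated knockdown cells, 468 ± 193 and 289 ± 69.8 with DMSO, and 379 ± 77.9 and 138 ± 27.2 with triptolide. The gene (ENSG00000160710.15_2) lies on chromosome 1 at 154554171 to 154600489 of GRCh37. Its log2 differences of -0.70 ± 0.33 (SE), -0.69 ± 0.33 and -1.46 ± 0.34 did not pass the edgeR test over all genes, with adjusted p = 1, 1 and 0.306. With the replicate block they were -0.67 ± 0.18, -0.65 ± 0.18 and -1.42 ± 0.18, at adjusted p = 0.117, 0.126 and 0.000108, so the difference under triptolide passed there. ADARB1, the related editing enzyme, stood at 6.18 ± 1.06 CPM in untreated control and 7.02 ± 3.21 in untreated knockdown cells, and ADARB2 at 0.315 and 0.198 CPM. Neither was called in any of the 8 comparisons.

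**Figure D1:**
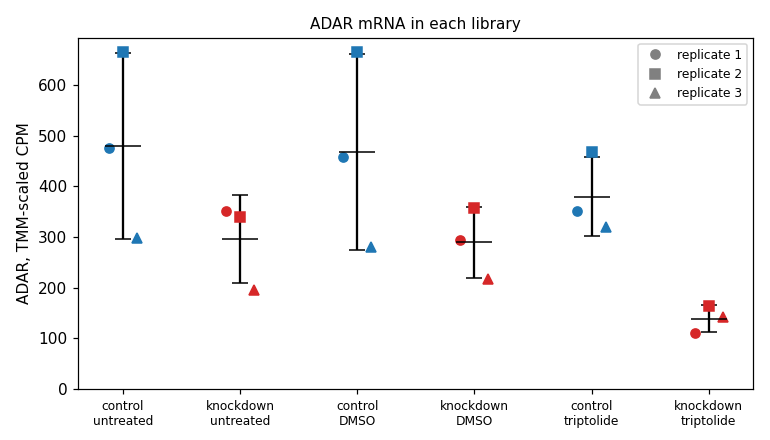
ADAR mRNA in TMM-scaled CPM (vertical axis, from 0) for each of the 6 groups, one symbol per library by replicate number, with the mean as a bar and the SD as whiskers. Knockdown libraries (red) lie below the control library (blue) of the same number in 9 of 9 pairs, while the groups overlap without triptolide.

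The knockdown was compared with control first without triptolide, to see which genes differ between the lines. The labels name no further knockdown line. Effects of the ADAR knockdown therefore cannot be told from other differences between the lines, and the SE covers the spread between replicate libraries only. Higher in knockdown cells, untreated and with DMSO alike, were CD36, a fatty acid and lipoprotein receptor, TFAP2B, a transcription factor of the AP-2 family, and GNAT3, the taste receptor G protein gustducin. Lower were IL12RB1, a subunit of interleukin receptors, CUBN, the vitamin B12 complex receptor cubilin, and KYNU, an enzyme of tryptophan breakdown. NOX1, an NADPH oxidase, CRYAB, a small heat shock protein, NPY1R, a neuropeptide Y receptor and estrogen-responsive gene, and RFX2, a transcription factor of ciliogenesis, were lower as well. IL12RB1 (ENSG00000096996.15_1, chromosome 19, 18169805 to 18209754) fell from 23.4 ± 5.18 to 0.0494 ± 0.0578 CPM untreated, a log2 change of -8.73 ± 0.57 (SE, n = 3 per group). RFX2 (ENSG00000087903.12_2, chromosome 19, 5993175 to 6199583) was 2.93-fold lower untreated and 3.52-fold lower with DMSO, at 44.2 ± 0.899 CPM in DMSO control and 12.5 ± 1.58 CPM in DMSO knockdown cells.

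TFAP2B (ENSG00000008196.12_1, chromosome 6, 50786436 to 50815332) rose from 1.61 ± 0.772 to 19.5 ± 4.11 CPM untreated, a log2 change of 3.61 ± 0.42, and was 10.4-fold higher with DMSO. CD36 (ENSG00000135218.17_2, chromosome 7, 79998891 to 80308593) was 5.77-fold and 5.82-fold higher. GNAT3 (ENSG00000214415.3_1, chromosome 7, 80087951 to 80141380) lies within the span of CD36 on the opposite strand, and stood at 2.49 ± 1.61 CPM in untreated knockdown against 0.0481 ± 0.0567 CPM in untreated control cells. The strand setting of the counting is not stated, so CD36 reads counted for GNAT3 were not excluded. Among the lower genes, the untreated log2 changes were -5.88 ± 0.85 for CUBN, -4.32 ± 0.67 for KYNU, -4.29 ± 0.49 for NOX1, -2.68 ± 0.39 for CRYAB and -2.02 ± 0.24 for NPY1R. The pseudogenes HNRNPKP1 (19.3-fold higher untreated) and PGAM1P8 (6.45-fold lower) were called too, and reads shared with their parent genes make their identity uncertain.

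Each comparison called 21 genes, 6 higher and 15 lower untreated and 9 higher and 12 lower with DMSO. Of these, 6 were higher and 10 lower in both, against 0.00254 and 0.00846 by chance, with 0 in opposite directions. With the replicate block each called 124, 64 higher and 60 lower untreated and 71 higher and 53 lower with DMSO, and 49 were higher and 37 lower in both. A fit of only the libraries compared called 5 untreated and 4 with DMSO. Single libraries left out lowered the untreated count to 12 without knockdown replicate 1, 12 without control replicate 3 and 11 without knockdown replicate 3, and the DMSO count to 12 without control replicate 2 and 12 without control replicate 3. Calls of GNAT3 ended without untreated control replicate 2 (adjusted p = 0.0527) and without any one DMSO control library (0.0627 to 0.0834). CUBN lost its untreated call without any one knockdown library (0.0517 to 0.0727) and its DMSO call without knockdown replicate 3 (0.0902). KYNU lost its untreated call in the same way (0.0546 to 0.07) and its DMSO call without knockdown replicate 1 (0.0706), and PGAM1P8 its untreated call without control replicates 1 or 3 or any knockdown library (0.0867 to 0.265). These fits had no block, so replicate numbers were unbalanced. With all libraries and the block, all 21 genes of each comparison were called again. The blocked untreated adjusted p was 5.25e-06 for GNAT3, 9.21e-08 for CUBN, 0.000172 for KYNU and 0.000487 for PGAM1P8.

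Few gene groups set the untreated lines apart. Fry called 0 of the 22 lists between the lines untreated, and 0 with DMSO, so the list calls here are those of camera. Targets of ATF4, the transcription factor of the integrated stress response, were lower at a median log2 of -0.24 over 32 genes, with 0 called singly and 0 when adjusted over the list alone (camera adjusted p = 0.000943, and adjusted p = 0.9 with an estimated correlation). TRIB3, a pseudokinase of that response, had -0.47 ± 0.21 and PSAT1, a serine synthesis enzyme, -0.42 ± 0.29. Replication-dependent histones had a median of 0.17 over 54 genes, which was -0.000315 with scaling to mitochondrial mRNAs (adjusted p = 0.000403, and adjusted p = 0.9 with an estimated correlation). Neither the ATF4 nor the histone list was called between the lines with DMSO. The ATF4 call ended without knockdown replicate 1 (adjusted p = 0.228) and reversed without control replicate 2 (0.997), and the histone call ended without control replicate 2 (0.172). NDUFV2, a complex I subunit, was the one member of the nuclear oxidative phosphorylation list called, -2.03 ± 0.35 untreated (adjusted p = 0.0228), with 1 lower when adjusted over the list alone. With DMSO it had -1.44 ± 0.33, not called over all genes (0.248) but lower when adjusted over the list alone and with the block (0.0113).

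With DMSO, interferon-stimulated genes had a median of 0.28 over 47 genes in knockdown against control cells (adjusted p = 0.00473, and adjusted p = 0.847 with an estimated correlation). IFI44 had 3.34 ± 1.83 and IFI44L 2.61 ± 2.15, and 0 members were called or passed when adjusted over the list alone. The list's mean level differed more between replicate numbers than between lines: 2.69 in DMSO control replicate 3 against 5.02 and 5.54 in the others, on the scale log2 (CPM + 1). With the replicate block the list was called untreated as well (adjusted p = 2.04e-11, and 0.92 with an estimated correlation), with medians of 0.30 untreated and 0.41 with DMSO. Blocked, RSAD2, an antiviral enzyme, and IFI44L were higher in each, and 4 members untreated and 3 with DMSO when adjusted over the list alone. The DMSO call without the block ended without knockdown replicates 1 (0.811) or 2 (0.792) and turned downward without control replicate 3 (0.0327). Leaving out a single library also unbalances the replicate numbers, so these changes cannot be told from differences between replicate numbers.

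Of the other lists with DMSO, mitochondrially encoded mRNAs were lower at a median of -0.58 over 13 genes (adjusted p = 9.12e-05, and adjusted p = 0.847 with an estimated correlation), with MT-CO3 at -0.58 ± 0.23. Their share of counts was 0.805 ± 0.0774% in DMSO knockdown and 1.13 ± 0.206% in DMSO control cells. Untreated it was 1.12 ± 0.347% in knockdown and 1.03 ± 0.375% in control cells, and the list was not called there. Genes of G2 and M phase had a median of 0.13 (adjusted p = 0.00298, and 0.847 with an estimated correlation), with CENPF at 0.47 ± 0.29, and the call ended without knockdown replicate 3 (0.117). Between the untreated lines the G2 and M list was not called. NF-kB targets had 0.14 (0.0311, and adjusted p = 0.847 with an estimated correlation), which ended without knockdown replicate 1 (0.896) or control replicate 3 (0.863). Edited mRNAs, which carry recoding sites or inverted Alu repeats, had a median of 0.10 over 24 genes (0.0311, and adjusted p = 0.452 with an estimated correlation), with AHR at 0.98 ± 0.40 and AZIN1, a known recoding target, at 0.18 ± 0.18. That call ended without control replicate 1 (0.13) and without knockdown replicates 2 (0.0664) or 3 (0.117). In these 4 lists 0 members were called, also when adjusted over the list alone. With the replicate block the NF-kB list was also called untreated (0.0273, and 0.92 with an estimated correlation), and with DMSO the DNA repair list (0.041, and 0.688) and the estrogen receptor list (0.028, and 0.688), of which 1 gene was higher.

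Under triptolide, which blocks transcription initiation through the TFIIH helicase XPB, the same comparison asked which differences between the lines remain. How much new RNA was still made was not measured. IL12RB1, KYNU, NOX1, CRYAB, NPY1R and RFX2 were again lower in knockdown cells, and CD36, GNAT3 and HNRNPKP1 higher. PGAM1P8 was not, at -1.14 ± 0.48 (SE, adjusted p = 1, and 0.372 with the block). GNAT3 stood at 3.83 ± 1.55 CPM against 0.0161 ± 0.0279 CPM, with 1 count over the control libraries, so no fold is given. RFX2, at a log2 change of -2.22 ± 0.19, fell from 43.9 ± 8.18 to 9.42 ± 0.989 CPM, and IL12RB1 was 80.7-fold lower. ITM2A (ENSG00000078596.10_1, chromosome X, 78615881 to 78623164), a membrane protein gene, rose from 2.82 ± 1.21 to 16.7 ± 5.28 CPM, 5.89-fold. FAM90A27P (ENSG00000189348.6_1, chromosome 19, 53780715 to 53788200) had 159 counts over the control libraries and 0 over the knockdown libraries, at least 59-fold lower against a floor of 3 counts over the group. TFAP2B, at 2.41 ± 0.898 against 0.651 ± 0.274 CPM, and CUBN, at 4.53 ± 1.77 against 21.2 ± 11.6 CPM, were not called there (adjusted p = 0.306 and 0.829) but passed with the block (0.0149 and 0.000578).

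The comparison called 14 genes by edgeR, 4 higher and 10 lower, and 133 with the replicate block, 78 higher and 55 lower. Of the genes called, 3 were higher and 8 lower in all 3 treatments (27 and 26 with the block). The count was 9 without knockdown replicate 1, 9 without knockdown replicate 3 and 9 with only the libraries compared. Single libraries left out ended the calls of KYNU (without any knockdown library, adjusted p = 0.0553 to 0.0712), CRYAB (without knockdown replicate 1, 0.0755, or 3, 0.124, or control replicate 3, 0.0565) and HNRNPKP1 (without control replicate 1, 0.0515). ITM2A lost its call without control replicates 1 (0.0897) or 3 (0.0997) or knockdown replicate 2 (0.073), and FAM90A27P without control replicates 1 (0.0838) or 3 (0.0971) or any knockdown library (0.0691 to 0.096). With all libraries and the block, all 14 genes were called again. The blocked adjusted p was 0.000245 for KYNU, 4.77e-05 for CRYAB and 1.01e-06 for HNRNPKP1.

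By camera at the preset correlation, gene groups differed between the lines under triptolide by small amounts. Fry and camera with an estimated correlation called 0 of the 22 lists. Cytoplasmic ribosomal protein mRNAs had a median of 0.18 over 76 genes (adjusted p = 2.06e-12, and 0.333 with an estimated correlation), with RPL38 at 0.35 ± 0.22. Nuclear oxidative phosphorylation genes had 0.16 (adjusted p = 3.48e-07, and 0.43 with an estimated correlation), although NDUFV2 had -1.69 ± 0.37 and was the 1 member lower when adjusted over the list alone. Estrogen receptor targets and luminal factors had 0.04 (0.0035, and adjusted p = 0.333 with an estimated correlation), and 2 were higher when adjusted over the list alone. ESR1, the estrogen receptor itself, had 0.70 ± 0.17 and TFF1, a secreted estrogen-induced peptide, 1.87 ± 0.61, both passing with the block (0.0043 and 0.000805). Lower were ZNF-named zinc finger genes at -0.20 over 454 genes (8.73e-07, and adjusted p = 0.382 with an estimated correlation), immediate early and short-lived mRNAs at -0.29 (7.72e-05, and 0.382), replication-dependent histones at -0.24 (0.00525, and 0.761) and G2 and M phase genes at -0.15 (0.0439, and 0.84), the second value of each being the adjusted p with an estimated correlation. NDC80, a kinetochore protein, was lower when adjusted over the list alone, at -0.97 ± 0.23 (0.00127 over all genes with the block), and 0 members of these 7 lists were called over all genes. With the block 3 estrogen receptor list genes were higher, and 3 zinc finger, 2 G2 and M phase and 1 oxidative phosphorylation genes lower. The interferon list passed with the block only (2.27e-06, and adjusted p = 0.521 with an estimated correlation), as did edited mRNAs (0.0479, and 0.314).

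Of these calls, that of the ribosomal proteins held without any one library. Without control replicate 2 those of the oxidative phosphorylation list (0.788) and the ZNF list (0.413) ended, and without control replicate 1 those of short-lived mRNAs (0.0625) and estrogen receptor targets (0.0513, also without knockdown replicate 3, 0.148). The histone and G2 and M calls reversed without knockdown replicate 1 (0.971 and 0.517) and ended without knockdown replicate 2 (0.101 and 0.776) or control replicate 3 (0.795 and 0.116, the latter reversed).

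Triptolide against DMSO asked which RNAs are lower or higher, relative to the others, after 16 h with this inhibitor of RNA polymerase II. Several messages of luminal identity fell in both lines. XBP1, a secretory and luminal transcription factor, had log2 changes of -3.83 ± 0.29 (SE) in control and -4.01 ± 0.29 in knockdown cells. FOXA1, a pioneer factor of luminal cells, was 9.27-fold and 9.96-fold lower, GATA3 3.4-fold and 2.9-fold, and ESR1 3.13-fold and 2.48-fold. MYC, a short-lived message, was 5.47-fold and 5.73-fold lower, MCL1, a labile BCL2 relative, 2.46-fold lower in knockdown cells, and BCL2L1, an apoptosis inhibitor, 3.09-fold and 3.22-fold lower.

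Of the 8 lower genes chosen by the rule, 7 were histone messages, whose genes are transcribed in S phase. H1-3 (ENSG00000124575.6_1, chromosome 6, 26234440 to 26235215) went from 137 ± 38.5 to 2.2 ± 0.843 CPM in control and from 128 ± 17.5 to 1.9 ± 0.519 CPM in knockdown cells, log2 changes of -5.96 ± 0.34 and -6.06 ± 0.34. The changes of H1-5 were -5.54 ± 0.54 and -5.89 ± 0.55, of H1-4 -5.03 ± 0.62 and -5.12 ± 0.62, of H2BC14 -4.72 ± 0.37 and -4.92 ± 0.37, and those of H3C12, H2BC4 and H3C7 lay between -4.95 and -4.24. Of 54 measured histone genes 42 were lower and 5 higher in control cells, and 42 and 6 in knockdown cells (43 and 5, 44 and 6 when adjusted over the list alone). Their share of counts went from 0.64 ± 0.0292% to 0.0409 ± 0.00716% and from 0.65 ± 0.128% to 0.0385 ± 0.0138%. Near-identical histone paralogs share reads, so a single member is less certain than the group. SNORD14E, a small nucleolar RNA and the other lower gene, went from 3.96 ± 2.18 to 0.138 ± 0.0351 CPM in control cells, a log2 change of -4.79 ± 0.83. In knockdown cells it went from 3.97 ± 1.88 to 0.045 ± 0.078 CPM, with 3 counts over the triptolide libraries, so no fold is given.

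Genes with the largest relative rises were near silent with DMSO. FLG2, a skin barrier gene (ENSG00000143520.6_1, chromosome 1, 152321211 to 152332482), had 0 counts with DMSO and reached 2.66 ± 0.978 and 2.3 ± 0.542 CPM, at least 92.5-fold and 84.7-fold higher. SLC9C2, a sodium/proton exchanger relative (ENSG00000162753.11_1, chromosome 1, 173469599 to 173572211), was at least 76.7-fold and 105-fold higher, against a floor of 3 counts over the group. MGAM2, MOBP, a myelin gene, TG, the thyroid hormone precursor, DACT1, PAPPA2 and the pseudogene PKMP3 rose from at most 0.0471 CPM to between 2.41 and 10.5 CPM. EGR1 and FOSB, immediate early transcription factors, were 18.7-fold and 11.3-fold higher in control cells, and ATF3, a stress-induced factor, 5.83-fold higher there and 4.34-fold in knockdown cells.

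By edgeR 6562 genes changed in control cells (3159 higher, 3403 lower) and 7583 in knockdown cells (3554 higher, 4029 lower). With the replicate block the counts were 11065 (5544 higher, 5521 lower) and 12112 (6152 higher, 5960 lower), and DESeq2 called 8047 (4654 higher, 3393 lower) and 9046 (5033 higher, 4013 lower). These changes are relative to the other genes. Scaled to mitochondrially encoded mRNAs, the median of all genes was -0.79 in control and -1.36 in knockdown cells, against 0.03 and 0.04 with TMM and -0.60 and -0.67 with library size alone. With that scaling 1063 genes were higher and 6008 lower in control, and 821 and 11443 in knockdown cells. The mitochondrial mRNAs themselves differed between the lines with DMSO. They took 1.13 ± 0.206% of counts in DMSO control and 0.805 ± 0.0774% in DMSO knockdown cells. Untreated they took 1.03 ± 0.375% and 1.12 ± 0.347%. The larger shift in knockdown cells thus cannot be told from a lower reference with DMSO, and is no measure of RNA loss.

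Both lines changed alike: 2692 genes were higher and 3053 lower in both, against 527 and 644 by chance, and 0 were called in opposite directions. With the block 4819 were higher and 4893 lower in both, against 1600 and 1550 by chance, and 2 went in opposite directions. Across the 21285 genes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.918 and rho = 0.909, and 89.1% had the same sign.

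**Figure D2:**
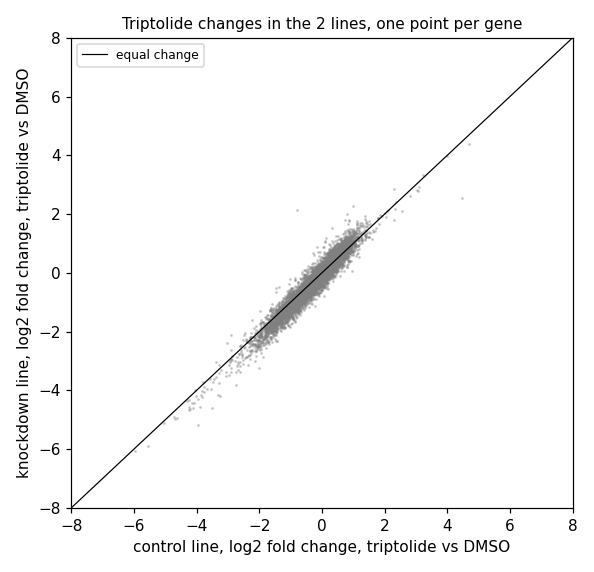
Log2 fold change of triptolide against DMSO in the control line (horizontal axis) and the knockdown line (vertical axis), one grey point per tested gene with a mean above 10 CPM, with a line of equal change. The points lie along the line, with r = 0.968 across the genes in that range.

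Among the lists, 7 fell in both lines under each of the scalings by TMM, RLE, library size and mitochondrial mRNAs. With library size alone and with mitochondrial mRNAs the median of all genes was below 0 as well. A fall of a list under those scalings therefore adds no separate support. Estrogen receptor targets and luminal factors had medians of -0.97 in control and -0.87 in knockdown cells, with 18 of 40 lower and 1 higher in each (19 and 1, 18 and 2 when adjusted over the list alone). Their camera adjusted p was 5.53e-06 and 5.72e-05, and the adjusted p was 0.0442 and 0.0996 with an estimated correlation (0.231 and 0.233 with the block). Genes of G2 and M phase had -0.81 and -0.95, with 26 and 36 of 54 lower (29 and 38 adjusted over the list alone), among them KIF11, a mitotic kinesin, 3.52-fold and 5.23-fold lower. S phase genes had -0.42 and -0.41, with 12 and 17 of 45 lower (11 and 17), among them POLD3, a DNA polymerase subunit, at -2.19 ± 0.27 and -2.49 ± 0.27. DNA repair and checkpoint genes had -0.60 and -0.71, with 21 and 28 of 55 lower (24 and 29) and ERCC6 3.26-fold and 3.87-fold lower. Zinc finger genes had -0.52 and -0.69, with 161 and 207 of 454 lower (178 and 225), and ZNF45 had -2.74 ± 0.21 and -3.39 ± 0.21. The mRNA decay machinery had -0.47 and -0.53, with 15 and 23 of 52 lower (15 and 24), and CNOT2, a deadenylase subunit, was 5.04-fold and 5.79-fold lower. Replication-dependent histones had -3.32 and -3.58. With the block, lower genes numbered 24 and 21 of the estrogen receptor list, 41 and 45 of G2 and M phase, 24 and 23 of S phase, 33 and 35 of repair, 230 and 277 of the zinc finger genes, 32 and 31 of decay and 43 and 44 of the histones.

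For these lists camera gave adjusted p = 6.5e-09 and 4.81e-12 (G2 and M), 0.00242 and 0.00195 (S), 2.94e-06 and 6.26e-07 (repair), 2.52e-08 and 4.81e-12 (zinc finger), 1.32e-05 and 3.45e-06 (decay) and 5.99e-20 and 8.87e-19 (histones). In the same order, the adjusted p was 0.372 and 0.237, 0.817 and 0.673, 0.225 and 0.154, 0.265 and 0.154, 0.26 and 0.178, and 0.0955 and 0.111 with an estimated correlation. Each of the 7 calls held without any one library.

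Messages of ribosomes and mitochondria rose relative to other genes. Cytoplasmic ribosomal proteins had medians of 0.64 in control and 0.81 in knockdown cells, which turned to -0.16 and -0.59 with scaling to mitochondrial mRNAs. Of 76 measured, 46 and 60 were higher and 1 lower in each (58 and 69, and 1, adjusted over the list alone), with RPS16 1.86-fold and 2.19-fold higher and RPL36A 5.43-fold and 5.9-fold lower. Nuclear oxidative phosphorylation genes had 0.57 and 0.72, turning to -0.31 and -0.74 with that scaling, where the list was no longer called (adjusted p = 0.375 and 0.523), and to -0.05 and -0.01 with library size alone. Of 66, 23 and 39 were higher (30 and 43 adjusted over the list alone), with SDHC, a complex II subunit, 1.75-fold and 1.89-fold higher and NDUFV2 3.01-fold and 3.57-fold lower. Mitochondrially encoded mRNAs, made by another polymerase, had 1.13 and 1.54, with 5 and 11 of 13 higher (7 and 13) and MT-ND3 2.72-fold and 3.24-fold higher, while mitochondrial ribosomal RNA rose to between 42.7 and 55.2% of counts. RNA polymerase III transcripts had 1.91 and 1.80, with 6 of 12 higher in each (8 and 8), RNU6-8, a spliceosomal RNA gene, at 2.08 ± 0.42 and 2.41 ± 0.42. With the block 70 and 73 ribosomal protein genes, 49 and 53 of nuclear oxidative phosphorylation, 8 and 12 mitochondrial mRNAs and 9 and 9 RNA polymerase III transcripts were higher.

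Camera gave adjusted p = 4.25e-11 and 5.5e-15 for ribosomal proteins, 5.53e-06 and 1.26e-08 for nuclear oxidative phosphorylation, 0.00385 and 6.15e-05 for mitochondrial mRNAs and 0.00077 and 0.000767 for RNA polymerase III transcripts. In the same order, the adjusted p was 0.225 and 0.149, 0.525 and 0.32, 0.729 and 0.427, and 0.213 and 0.154 with an estimated correlation. Leaving out control triptolide replicate 3 ended the call of mitochondrial mRNAs in control cells (0.188), and no other single library ended one of these calls.

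Several of the other lists held members that went both ways. Of the p53 targets, PMAIP1, a cell death gene, rose 4.89-fold and 3.5-fold and MDM2, the p53 ubiquitin ligase, fell 2.76-fold and 3.58-fold (medians -0.17 and -0.16, adjusted p = 0.744 and 0.393). ATF4 targets had medians of -0.19 and -0.19 (0.412 and 0.433), with ATF3 higher and TRIB3 5.31-fold and 5.04-fold lower. Immediate early and short-lived mRNAs had 0.13 and -0.03 (0.744 and 0.763), with 11 higher and 10 lower in control and 9 and 12 in knockdown cells (12 and 10, 9 and 13 adjusted over the list alone), or 18 and 18, and 16 and 17, with the block. Mesenchymal and basal markers had 0.55 and 0.48 (0.718 and 0.393), with TWIST1, a transcription factor, 9.4-fold and 9.46-fold lower and SNAI1 3.01-fold and 3.09-fold higher. BCL2 family genes had -0.07 and -0.10 (0.744 and 0.433) and NF-kB targets 0.36 and -0.01 (0.473 and 0.969). Glycolysis enzymes had 0.28 and 0.38 (0.253 and 0.0888), small nucleolar RNA host genes 0.08 and 0.31 (0.744 and 0.969), RNA polymerase II and TFIIH subunits 0.04 and -0.12 (0.872 and 0.914) and edited mRNAs -0.01 and -0.09 (0.744 and 0.592). Interferon-stimulated genes had -0.62 and -0.92 (0.473 and 0.235), and with the block adjusted p = 0.0152 and 0.00145, and 0.8 and 0.594 with an estimated correlation. Lower members of that list numbered 3 and 5, and 18 and 24 with the block, where 5 and 6 were higher. IRF9, a factor of interferon signalling, fell 8.27-fold and 6.95-fold. ADAR itself fell 2.09-fold in knockdown cells (adjusted p = 0.0186), a call that ended without triptolide knockdown replicate 1 (0.0746) or DMSO knockdown replicate 2 (0.0691), and had -0.30 ± 0.33 in control cells (0.524).

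The interaction asked whether the triptolide change differed between knockdown and control, the question of RNA stability that the series title raises. As RNA synthesis was not measured, a relative change need not be a rate of RNA loss. No single gene passed: edgeR called 0, with 199 at an unadjusted p under 0.05, and 0 were called with the block (841) and by DESeq2 (306). ADAR had -0.76 ± 0.47, and the genes with the largest triptolide changes had small differences, such as H1-3 at -0.10 ± 0.40 and H1-5 at -0.35 ± 0.64. As groups, ribosomal proteins had a larger relative rise in knockdown cells (median difference 0.15, -0.49 with scaling to mitochondrial mRNAs) and G2 and M phase genes a larger fall (-0.25). Camera gave adjusted p = 6.45e-07 and 1.87e-06 for these, and the adjusted p was 0.593 and 0.593 with an estimated correlation. Fry gave adjusted p = 0.828 for both and called 0 lists, so these group differences rest on the preset correlation. In the data simulated from the blocked fit, edgeR without the block found a 4-fold interaction for 48% of genes and a 2-fold interaction for 4%, with 0 false calls. With the block it found 92% and 40%, with 8 false calls.

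DMSO against untreated tested the solvent. The list calls are those of camera, as fry called 0 of the 22 lists in either line. In control cells ATF4 targets were lower at a median of -0.21 (adjusted p = 0.000738, and 0.969 with an estimated correlation) and histones had 0.13, or -0.08 with scaling to mitochondrial mRNAs (0.00894, and adjusted p = 0.969 with an estimated correlation). In knockdown cells mitochondrially encoded mRNAs were lower at -0.90 over 13 genes (1.3e-12, and adjusted p = 0.335 with an estimated correlation), with MT-ND5 at -1.61 ± 0.60. Untreated knockdown replicate 1 had 7.23% of its counts in MT-RNR1, a mitochondrial ribosomal RNA, against 1.86 to 3.69% in the other untreated and DMSO libraries. RNA polymerase III transcripts were lower at -0.98 (5.47e-06, and adjusted p = 0.103 with an estimated correlation), with VTRNA2-1 at -1.73 ± 0.65. Small differences passed for G2 and M phase (0.14, adjusted p = 6.06e-05), S phase (0.10, 0.0146), repair (0.07, 0.0225) and histone genes (-0.10, or 0.46 with scaling to mitochondrial mRNAs, 0.00222), and for each of these 4 the adjusted p was 0.848 with an estimated correlation.

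No gene passed over all genes or, apart from 1 lower small nucleolar RNA host gene in knockdown cells (SNHG22, -2.26 ± 0.54), when adjusted over a list alone. By edgeR 0 were called in control (117 at an unadjusted p under 0.05) and 0 in knockdown cells (202), 0 with the block (271 and 708) and 0 by DESeq2 (172 and 298). Of the list calls, that of mitochondrial mRNAs held without any one library, and that of RNA polymerase III transcripts ended without untreated knockdown replicate 1 (0.0524). In control cells the ATF4 call ended without DMSO replicate 1 (0.978) and reversed without untreated replicate 2 (0.431), and the histone call ended without untreated replicate 2 (0.694) or DMSO replicates 2 (0.482) or 3 (0.178). In knockdown cells those of S phase (0.244) and repair genes (0.413) ended without untreated replicate 1, those of G2 and M phase (0.265) and repair genes (0.22) without untreated replicate 2, where S phase reversed (0.435), and those of G2 and M phase (0.0927) and repair (0.773) without DMSO replicate 3, where S phase reversed (0.576). The histone call there ended without untreated replicate 3 (0.156) and reversed without DMSO replicate 1 (0.567). With the block, interferon-stimulated genes passed in both lines (0.0342 and 4.07e-05, and 0.967 and 0.754 with an estimated correlation) and nuclear oxidative phosphorylation genes in knockdown cells (0.00779, and 0.847).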

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

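Of the tests below, those of a few genes of the interferon list, of scaling to mitochondrial mRNAs, of slopes with same-numbered pairs parted and of uncalled genes of a chromosome arm were chosen after the result was seen, as was the SE over pairs as the spread of the list medians. Differences between the lines in the triptolide change were tested by the interaction, and 8 lists passed with camera at the preset correlation. Median differences, knockdown minus control, were 0.153 for cytoplasmic ribosomal proteins, -0.21 for zinc finger genes, -0.248 for G2 and M phase genes, 0.147 for nuclear oxidative phosphorylation genes and 0.414 for mitochondrially encoded mRNAs. They were -0.26 for NF-kB targets (adjusted p = 0.0121), -0.204 for immediate early and short-lived mRNAs (0.0377) and -0.189 for histones (0.0377, and 0.0679 with the block). With the block interferon-stimulated genes (median -0.15, 0.0324, and adjusted p = 0.683 with an estimated correlation) and p53 targets (-0.16, 0.034, and 0.405) passed as well. The adjusted p was 0.593 or 0.606 for each of the 8 with an estimated correlation, and 0.828 for each with fry. Leaving out control triptolide replicate 2 ended the calls of zinc finger genes (0.256), nuclear oxidative phosphorylation (0.896) and mitochondrial mRNAs (0.407), and that of G2 and M phase ended without knockdown triptolide replicate 1 (0.117) or control triptolide replicate 3 (0.475). The histone call reversed without knockdown triptolide replicate 1 (0.673) or control triptolide replicate 3 (0.857) and ended without 5 others, and those of NF-kB targets and short-lived mRNAs ended without 6 and 8 single libraries. With scaling to mitochondrial mRNAs the median of all genes was -0.616, a value that includes the difference between the lines in those mRNAs with DMSO.

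Reads that mapped to more than one place, which the gene counts do not use, took 18.4% of reads in triptolide control libraries (SD 4.19) against 12.8% with DMSO, and 17.6% in triptolide knockdown libraries (SD 3.52) against 12.2% (each n = 3).

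The first pattern weighed is the larger triptolide change in knockdown cells among genes with a mean of at least 10 CPM. The slope was that of the principal axis, the line along which the control and knockdown changes spread most. It was 1.13 over these 8675 genes but 1.04 over all 21285 tested genes, so the excess over 1 was smaller there. Over the 8675 genes, 2 of the 3 replicate numbers had a slope above the bound set beforehand (1.17, 1.12 and 1.04). Splits of the libraries into other groups gave a slope as far from 1 in 49 of 200 cases, the highest being 1.31, but of the 32 that part all same-numbered pairs 1, the real one, did so, the highest other rounding to 1.13 as well. As these disagree, chance differences between libraries stay open, and so does a single replicate number: it needed a slope above 1 in at most 1 of the 3, which was not seen, but the bound set to exclude it was missed by the third. A biological difference in RNA loss between the lines remains open.

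The second pattern is the higher level of interferon-stimulated genes in knockdown cells with the replicate block. With the block, camera also called this list for DMSO against untreated in both lines, so its calls were not limited to the knockdown comparisons. The mean of the list was higher in the knockdown library in 9 of 9 same-numbered pairs. A difference within pairs leaves out replicate number by construction, so this does not test a difference between replicate numbers. A few genes alone would leave most of the list unchanged. The blocked medians were 0.299 untreated, 0.406 with DMSO and 0.23 with triptolide (SE 0.0991, 0.186 and 0.0651 over pairs). Of 47 genes 42, 40 and 39 were higher. With TMM scaling these values argue against a few genes alone, although 0.23 passed the bound of 0.2 by less than its SE. Scaling stays open by the same bound: the lowest blocked median was 0.257 (SE 0.174) with library size alone and 0.106 (SE 0.184) with scaling to mitochondrial mRNAs. Without the block that scaling gave -0.089 untreated, 0.78 with DMSO and -0.0175 with triptolide. In the blocked fit that scaling moved all genes by -0.171, 0.593 and -0.0156, and the list stood at 0.277, 0.454 and 0.287 relative to them, which a shift shared by all genes leaves unchanged by construction and which is no test of scaling. The adjusted p was 0.92, 0.537 and 0.521 with an estimated correlation in that fit, and the cause of the difference remains open.

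For the counts of called genes, other splits of the same libraries were tried. The 10 splits of 6 libraries are too few for a share under 0.05. In knockdown against control, 1 of 10 splits gave as many calls untreated (real 21, highest other 0), with DMSO (21, 0) and with triptolide (14, 3), and 1 of 10 in triptolide against DMSO in control (6562, 0) and knockdown cells (7583, 0). Among the 4 splits that part all same-numbered pairs the highest other was 0, and the split with 3 calls keeps a pair together. For DMSO against untreated, 10 of 10 splits gave as many as the real 0, the highest other being 0 in both lines, and for the interaction 100 of 100 splits did. Any split reaches a real count of 0, so these counts test nothing. For the interaction 5 of the 100 splits had any call, and the highest other was 63. The split with 63 calls parts all same-numbered pairs and was the 1 with a call among the 18 that do, while the 82 that keep a pair gave at most 6. The possible splits include a swap of the lines in a single treatment, which adds the line differences of both treatments instead of comparing them. Whether the split with 63 calls is that swap was not checked, so no conclusion is drawn from it.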

How the results depend on the processing

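The named genes stayed on their side of the threshold, without a reversed call, in 1700 of 1769 alternatives, with 59 calls lost, 9 gained and 1 reversed, and lists in a comparison in 2338 of 2684, with 163 lost, 157 gained and 26 reversed. Of the 1700 and 2338, the sign changed with neither value called in 87 and 237, so direction was not kept there. With the block, the calls of named genes and of lists by camera changed only where printed beside the results, and more members of most lists were called under triptolide. The cause of the differences was not tested except where fewer libraries or genes enter. RLE factors moved no count past 1.5 times, and strict filtering left some named genes untested. Depth limits genes near 1 CPM.

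Called genes in the knockdown untreated, with DMSO and with triptolide were 52, 42 and 48 with DESeq2 and 91, 74 and 60 without a filter, where the interaction had 3 and DMSO in knockdown cells 25. With only the libraries compared they were 5, 4 and 9, and 19 calls of named genes ended. With the replicate block they were 124, 124 and 133, and triptolide had 11065 in control and 12112 in knockdown cells. Against a fold of 1.5 triptolide had 3659 and 4403. With scaling to mitochondrial mRNAs the knockdown in triptolide had 9 and triptolide in knockdown cells 12264, where ADARB1 turned to -1.15.

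The comparisons of 8 that called a list were as follows. By default: interferon 1, NF-kB 2, ATF4 2, p53 0, S phase 3, G2 and M 6, repair 3, estrogen receptor 3, mesenchymal 0, short-lived 2, BCL2 0, mitochondrial mRNAs 5, ribosomal proteins 4, glycolysis 0, oxidative phosphorylation 4, histones 7, zinc finger 4, host genes 0, polymerase III 3, decay 2, polymerase II 0 and edited 1. With library size alone: NF-kB 1, repair 5 and polymerase III 5. Without a filter: interferon 4, p53 2, BCL2 2, histones 3, host genes 1, polymerase II 1 and edited 3. With at least 1 CPM in 3 libraries: interferon 2, NF-kB 1, p53 1, glycolysis 1 and edited 0. With only the libraries compared: interferon 2, NF-kB 1 and p53 1. With the replicate block: interferon 8, p53 1 and edited 2. With an estimated correlation: estrogen receptor 1 and 0 for interferon, NF-kB, ATF4, S phase, G2 and M, repair, short-lived, mitochondrial mRNAs, ribosomal proteins, oxidative phosphorylation, histones, zinc finger, polymerase III, decay and edited. With fry: interferon 0, NF-kB 0, ATF4 0, p53 1, S phase 1, G2 and M 2, mesenchymal 1, short-lived 0, mitochondrial mRNAs 1, ribosomal proteins 2, oxidative phosphorylation 2, histones 2 and zinc finger 2.

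Leaving out a library, or all of a number, gave 4 to 16, 3 to 18 and 2 to 17 calls in the knockdown untreated, with DMSO and with triptolide, and 3518 to 6128 for triptolide vs DMSO, control, and 4513 to 7258 for triptolide vs DMSO, knockdown. List counts ran from 0 to 4 (interferon, ATF4, short-lived, glycolysis), 0 to 3 (NF-kB), 0 to 1 (p53, host genes, polymerase II, edited), 2 to 5 (S phase, repair), 2 to 6 (oxidative phosphorylation, zinc finger) and 2 to 4 (decay).

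Adjusted p of lists that reversed ran, for the knockdown untreated, from 4.32e-12 to 0.942 (interferon), 1.36e-05 to 0.997 (ATF4), 1.67e-05 to 0.942 (S phase), 0.0254 to 0.929 (short-lived) and 0.00427 to 0.922 (ribosomal proteins). With DMSO it ran from 9.6e-19 to 0.811 (interferon), and with triptolide from 0.0105 to 0.776 (S phase), 1.48e-12 to 0.776 (G2 and M), 1.74e-05 to 0.971 (mitochondrial mRNAs) and 9.15e-11 to 0.971 (histones). For the interaction it ran from 1.68e-06 to 0.841 (interferon) and 3.33e-08 to 0.857 (histones). For DMSO in control cells the ranges were 3.11e-15 to 0.372 (interferon), 0.0218 to 0.884 (NF-kB), 3e-08 to 0.978 (ATF4), 0.0158 to 0.98 (G2 and M), 0.00992 to 0.962 (short-lived) and 0.00224 to 0.98 (glycolysis), and in knockdown cells 7.04e-14 to 0.32 (interferon), 3.93e-10 to 0.576 (S phase), 0.000293 to 0.971 (ribosomal proteins) and 1.15e-08 to 0.567 (histones).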

Other observations

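Genes of the short arm of chromosome 18 were lower in knockdown cells, an observation made from the genes called with the replicate block and tested on the same data. Over 94 tested genes the median log2 difference was -0.59 untreated, -0.50 with DMSO and -0.56 with triptolide, the lowest of 41 arms with at least 20 tested genes. NDUFV2 and NDC80, 2 of its genes, were picked out above by the list rule. The next lowest arm, 5p, had -0.29, -0.22 and -0.37 over 181 genes. The highest of these medians, -0.497, restates the observation and does not test its cause. The 72 genes of the arm called in none of the 3 comparisons, a test chosen after the result was seen, had -0.43, -0.366 and -0.522, so the difference was not limited to the called genes. A lower copy number of the arm in the knockdown line is therefore a candidate explanation. GC content and gene length argue against themselves as the cause, as the median was -0.517 after their trend was taken away, and a single pair of libraries does too, with 9 of 9 pairs under -0.1. RNA alone cannot show copy number, and the knockdown and the arm cannot be separated in these lines, so a lower copy number stays a hypothesis.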
